A study of Homo sapiens with 9 samples.

How the data were processed

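Total RNA of cells labelled HT29, a human colorectal cancer line, was sequenced after rRNA depletion in 9 libraries, 3 each of Control, DNMT1 knockdown and DNMT3B knockdown cells. Per the labels' protocols, stable knockdown was made with lentiviruses and puromycin selection, RNA was extracted with a column kit after lysis in TRIzol, rRNA was removed with an MGI kit, and libraries were made with a Vazyme kit for MGI sequencers. The authors deposited 1 table of raw read counts per gene symbol, which had not been scaled. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the human build GRCh38 (hg38); their versions, their settings, the gene annotation and the use of strand in counting are not given in the sources used here. Symbols were therefore taken as deposited, and values of antisense, overlapping and near-identical genes are reported as uncertain. The removal of rRNA leaves RNAs without a poly(A) tail, such as histone mRNAs and small structural RNAs, in the counts.

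The table held 25886 symbols, of which 3310 had no count in any library, and 0 of its columns lacked a sample. Groups came from the sample labels. Total counts in M (1e6) were 26.9 to 33.7 per library in Control (mean 30.6 ± 3.42, SD, n = 3), 23.4 to 24.2 in DNMT1 knockdown (23.9 ± 0.396) and 18.8 to 26 in DNMT3B knockdown (23 ± 3.76). A count of 0 allows up to 3 counts, which is 0.0891 to 0.16 counts per 1e6 counts (CPM) depending on the library. Such floors and the counting intervals (exact, 95%) cover counting error only. Counts of rRNA genes made up 0.597 to 0.771% of each library. No mitochondrially encoded mRNA was in the table, so that list was not tested.

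The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group, 16660 in all, were scaled by TMM and fitted with the quasi-likelihood model over all 9 libraries, so that the 3 groups shared 1 estimate of the spread (6 residual degrees of freedom, 25.4 prior degrees of freedom, common biological coefficient of variation 2.96%). A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes, and changed at least 2-fold where the absolute log2 fold change was also at least 1. Unless another test is named, every adjusted p is from this edgeR fit. Levels are given as mean ± SD in CPM of the TMM-scaled library size, and ± after a log2 fold change is its standard error. The comparisons were each knockdown against Control, and DNMT1 knockdown against DNMT3B knockdown, which tests the difference between them. For the targeted genes an exact two-sided permutation test of CPM was also run, whose smallest possible p with 3 against 3 libraries is 0.1.

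Before the data were examined, 29 gene lists were fixed for the cell type and the perturbation, and the 28 with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists. The list tests were repeated with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Members of each list were counted by their edgeR adjusted p over all tested genes and, separately, adjusted over the list alone. The genes to be named were also set beforehand by rule. For each knockdown they were DNMT1, DNMT3B and DNMT3A, the 8 largest rises and 8 largest falls among called genes with at least 2 CPM in the higher group and no overlap between the libraries of the groups, and up to 3 called members with the smallest adjusted p from each list that was called or had at least 3 called members. For the direct comparison the rule took 5 genes per direction, and for genes changed alike in both knockdowns the 5 per direction with the largest smaller change. Genes named outside the rule are said to have been chosen after their values were seen.

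Gene coordinates are from the GRCh38 annotation, in which 25574 of the 25886 symbols (98.8%) were found. The overlap of calls was set beside the overlap of independent lists, and the correlation, sign and covariance of the log2 fold changes beside 20 simulations of unchanged groups against the same 3 Control libraries. The alternatives tried were DESeq2 1.42.0, limma-voom, DESeq2 size factors, no TMM scaling, no low-count filter, at least 1 CPM in 3 libraries, a mean of at least 2 CPM, fits of only the groups compared, removal of small RNA and histone genes before scaling, the replicate number as a block, and leaving out each library in turn. Thinning every library to the smallest total, 18.8 M counts, was added after the data had been seen.

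The scripts were tested on simulated data. With known changes simulated for DNMT1 knockdown against Control among 16325 genes, edgeR recovered 72.9% of genes changed 1.25-fold, 84% of those changed 1.5-fold, 93.9% of those changed 2-fold and 100% of those changed 4-fold, and 7 calls (3.95%) were false. In the simulated DNMT3B knockdown comparison, which held no change, 0 genes were called by edgeR, DESeq2 or voom. With the S phase list shifted 1.2-fold in a simulation of 16660 genes for DNMT1 knockdown against Control, camera called that list and 0 of 27 others. Genes were simulated independently of one another, so this result cannot weigh false list calls where genes vary together.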

Results

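Cells labelled HT29, an established human colorectal adenocarcinoma line, were profiled by RNA sequencing of rRNA-depleted RNA in 3 Control, 3 DNMT1 knockdown and 3 DNMT3B knockdown libraries. DNMT1 copies DNA methylation onto newly replicated strands, and DNMT3B can methylate DNA that carried no mark. The series was designed around the lowered DNMT1 and DNMT3B seen under proteasome inhibitors. Its comparisons ask how the transcriptome differs when either enzyme is targeted for knockdown. Libraries held 18.8 to 33.7 M counts, where M is 1e6, with Control libraries the deepest as a group (30.6 ± 3.42 M, SD, n = 3). Across genes, libraries of one group correlated at 0.9957 to 0.9971 and libraries of different groups at 0.9886 to 0.9902. These correlations describe genes, which are not independent replicates. The first principal component (38.7% of the variance) ran from -27.5 to -25.5 in Control libraries and from 7.24 to 19.7 in the knockdowns. The second (31.4%) ran from -24.4 to -22.4 with DNMT1 knockdown and from 17.5 to 19.3 with DNMT3B knockdown. Each pair of replicates differed by more than sampling noise (chi-square per degree of freedom 1.8 to 3.7), so each library was counted once. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

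DNMT1 mRNA was reduced to 55% of Control in the DNMT1 knockdown, and DNMT3B mRNA to 49.9% of Control in the DNMT3B knockdown. DNMT1 (chromosome 19, 10133346 to 10194953, GRCh38) fell from 458 ± 10.3 to 252 ± 4.68 CPM (log2 fold change -0.86 ± 0.033, adjusted p = 2.83e-20). DNMT3B (chromosome 20, 32762385 to 32809356) fell from 61.3 ± 1.17 to 30.5 ± 2.45 CPM (adjusted p = 1.49e-17). DNMT3B stood at 64.2 ± 0.324 CPM in the DNMT1 knockdown, not distinguishable from Control (adjusted p = 0.22). DNMT1 rose slightly in the DNMT3B knockdown, to 488 ± 1.95 CPM (107% of Control, adjusted p = 0.0171). This call was lost without Control replicate 1 (log2 fold change 0.08, adjusted p = 0.0804). DNMT3A (chromosome 2, 25227874 to 25342590), the other de novo methyltransferase, fell from 36.0 ± 1.02 to 24.7 ± 1.56 CPM with DNMT3B knockdown (68.9% of Control, adjusted p = 4.07e-10) and was at 37.3 ± 1.03 CPM with DNMT1 knockdown (adjusted p = 0.432). UHRF1, which recruits DNMT1 to replicating DNA and was chosen after its values were seen, fell to 91.1% of Control with DNMT1 knockdown (adjusted p = 0.00182) and to 78.7% with DNMT3B knockdown (adjusted p = 6.87e-10). In the direct comparison DNMT3A was 1.50-fold higher with DNMT1 than with DNMT3B knockdown (adjusted p = 9.31e-11). The exact permutation p was 0.1 for each targeted gene in its own knockdown, the smallest that 3 against 3 libraries can give.

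**Figure D1:**
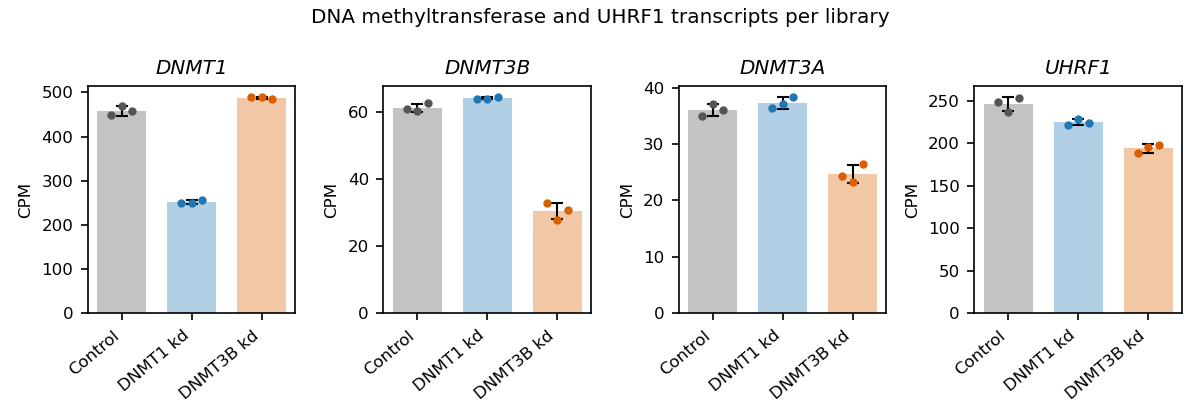
CPM of DNMT1, DNMT3B, DNMT3A and UHRF1 (y axes, from 0) in Control, DNMT1 knockdown (kd) and DNMT3B knockdown libraries, with points for libraries, bars for group means and error bars for SD (n = 3). DNMT1 lies at 248.5 to 257.1 CPM in its knockdown against 447.9 to 468.5 CPM in Control, and DNMT3B at 27.9 to 32.8 CPM in its knockdown against 60.4 to 62.6 CPM.

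Against Control, DNMT1 knockdown changed 6956 of 16660 tested genes (41.8%), and the largest rises were in genes with little or no expression in Control cells. CLSTN2 (chromosome 3, 139935185 to 140577397), a calsyntenin of the cadherin superfamily, rose 108-fold, from 0.462 ± 0.11 to 51.4 ± 0.264 CPM (log2 fold change 6.76 ± 0.098, n = 3 per group, edgeR adjusted p = 1.34e-31). TGFB2 (chromosome 1, 218345336 to 218444619), a TGF-beta ligand, rose 19.1-fold to 33.5 ± 0.378 CPM. NRP1 (chromosome 10, 33177493 to 33334667), a receptor for semaphorins and VEGF, fell from 132 ± 2.33 to 31.9 ± 0.266 CPM, 4.12-fold lower (adjusted p = 2.26e-27). CD36, a fatty acid receptor, was 5.23-fold lower, at 0.683 ± 0.0598 CPM.

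Further large rises were AOAH, MYH13 (53.5-fold), EHF (24.1-fold), LYPLAL1-AS1 (36.3-fold) and ZC3H11B (25.8-fold). AOAH, which encodes a lipopolysaccharide-degrading enzyme, had 165 counts over the DNMT1 knockdown libraries and 2 over the Control libraries, a depth-adjusted ratio of 106 with an exact 95% interval of 28.9 to 882. MYH13 belongs to a family of similar myosin genes, LYPLAL1-AS1 is named as an antisense RNA and ZC3H11B is a close copy of ZC3H11A, so their values are uncertain. EHF, an epithelial ETS factor, rose from 0.128 ± 0.0737 to 3.27 ± 0.567 CPM. The other large falls were in ZNF804A (3.14-fold lower), CAVIN2 (2.62-fold), ARHGAP24 (2.57-fold), SLC9A9 (2.28-fold), CCN2 (2.26-fold) and CSTA (2.23-fold). CCN2, known as connective tissue growth factor, went from 9.34 ± 0.451 to 4.12 ± 0.249 CPM.

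Fixed lists of proteasome subunits, the unfolded protein and integrated stress response, S phase and G2/M genes were lower with DNMT1 knockdown. Camera called them at the preset correlation but not at the estimated one. By fry, which does not compare a list with other genes, they were lower too (fry adjusted p = 0.0068, 7.16e-05, 0.000523 and 0.000692, in that order). Of 39 proteasome subunits, 32 fell and 1 rose (33 and 1 adjusted over the list alone), by a median log2 of -0.15 (camera adjusted p = 2.05e-07; adjusted p = 0.337 with an estimated correlation). PSMB5, the subunit bound by bortezomib, fell from 117 ± 4.52 to 93.2 ± 6.9 CPM, and PSMC3 fell from 146 ± 6 to 118 ± 2.92 CPM. In the unfolded protein and integrated stress response list, 16 of 33 genes fell and 2 rose (18 and 2 adjusted over the list alone; adjusted p = 9.24e-07; adjusted p = 0.201 with an estimated correlation). SLC7A11, the cystine transporter, fell from 190 ± 4.13 to 88.9 ± 2.7 CPM (log2 fold change -1.09 ± 0.036), with TRIB3 (-0.69) and the serine synthesis enzyme PSAT1 (-0.60) also lower. S phase and DNA replication genes fell in 31 of 48 cases and rose in 2 (33 and 2 adjusted over the list alone; adjusted p = 7.26e-07; adjusted p = 0.207 with an estimated correlation). Among them were RRM2 (-0.33), PCNA (-0.38) and POLD1 (-0.25). G2/M genes fell in 23 of 43 cases (26 adjusted over the list alone; adjusted p = 1.61e-05; adjusted p = 0.207 with an estimated correlation). CDK1 was at -0.38 and AURKA at -0.31. CDC25B, a phosphatase that activates CDK1, rose by 0.33, the 1 member of that list that rose over all genes (2 adjusted over the list alone).

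Lists of lipid synthesis and oxidative phosphorylation genes also fell. In the cholesterol and fatty acid list 19 of 33 genes fell and 0 rose (22 and 3 adjusted over the list alone; adjusted p = 6.07e-06; adjusted p = 0.223 with an estimated correlation). The sterol demethylase CYP51A1 was at -0.28. Nuclear-encoded oxidative phosphorylation genes fell in 31 of 52 cases and rose in 2 (32 and 2 adjusted over the list alone; adjusted p = 1.61e-05; adjusted p = 0.598 with an estimated correlation). They were led by the cytochrome oxidase subunits COX7C (-0.74) and COX7A2 (-0.56). Fry did not call the oxidative phosphorylation list (fry adjusted p = 0.0514). NF-kB and inflammatory genes fell in 9 of 23 cases and rose in 2, also when adjusted over the list alone (adjusted p = 0.0355; adjusted p = 0.344 with an estimated correlation). NFKB1 was at -0.28 and TRAF1 at -0.68. Without a low-count filter the adjusted p of this list was 0.0502. Replication-dependent histone genes, whose near-identical copies make single values uncertain, fell in 19 of 43 cases and rose in 4, also adjusted over the list alone (adjusted p = 0.031; adjusted p = 0.896 with an estimated correlation). The histone call was lost without Control replicate 1, Control replicate 3 or DNMT1 knockdown replicate 2 (adjusted p up to 0.0858). Fry did not call the histone list (fry adjusted p = 0.259). The DNA methylation machinery list, which contains the targeted gene itself, fell in 11 of 26 cases and rose in 5 (11 and 6 adjusted over the list alone; adjusted p = 0.0376; adjusted p = 0.211 with an estimated correlation). Without DNMT1 knockdown replicate 2, or with at least 1 CPM asked of 3 libraries, that call was lost (adjusted p up to 0.0676).

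Zinc finger, WNT and interferon-stimulated lists rose with DNMT1 knockdown. Of 392 numbered ZNF genes, 145 rose and 51 fell (147 and 52 adjusted over the list alone; adjusted p = 0.000978; adjusted p = 0.201 with an estimated correlation). ZNF608 went from 32.3 ± 0.297 to 70.2 ± 1.5 CPM, ZNF134 from 1.62 ± 0.215 to 9.63 ± 0.365 CPM and ZNF83 from 3.68 ± 0.0869 to 12.3 ± 0.92 CPM. In the WNT and intestinal stem cell list 9 of 22 genes rose and 5 fell, also adjusted over the list alone (adjusted p = 0.031; adjusted p = 0.223 with an estimated correlation). The crypt transcription factor SOX9 rose from 115 ± 2.26 to 179 ± 8.02 CPM and CD44 from 485 ± 12.2 to 641 ± 23.1 CPM. Interferon-stimulated genes rose in 15 of 42 cases and fell in 2, also adjusted over the list alone (adjusted p = 0.0446; adjusted p = 0.207 with an estimated correlation). BST2, which tethers budding viruses, went from 0.871 ± 0.193 to 4.03 ± 0.49 CPM, OAS1 from 0.826 ± 0.225 to 2.82 ± 0.299 CPM and IFI27 from 0.979 ± 0.0937 to 2.96 ± 0.238 CPM. The interferon call was lost without Control replicate 2 or 3, without any one of the DNMT3B knockdown libraries, and under other low-count filters (adjusted p up to 0.0879).

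The other lists did not pass the test with DNMT1 knockdown. Counts of members higher and lower were 5 and 13 of 30 p53 target genes (adjusted p = 0.101; 6 and 15 adjusted over the list alone), 11 and 7 of 34 imprinted genes (adjusted p = 0.827), 8 and 5 of 39 genes reported as promoter-methylated in colorectal cancer (adjusted p = 0.881), and 4 and 3 of 18 germline genes (adjusted p = 0.989). They were 6 and 3 of 18 MHC class I genes (adjusted p = 0.827) and 4 and 1 of 9 endogenous retroviral genes (adjusted p = 0.827). All but the p53 counts were alike when adjusted over the list alone. Of the p53 target genes, MDM2 fell from 333 ± 6.53 to 247 ± 5.27 CPM, while PLK2 rose from 43.6 ± 1.62 to 57.2 ± 1.96 CPM and EDA2R, a receptor of the TNF family, from 0.0654 ± 0.0298 to 1.26 ± 0.13 CPM. Within the other lists, the WNT antagonist DKK1 fell from 581 ± 22.7 to 386 ± 9.78 CPM. RASSF2 rose from 10.5 ± 0.68 to 16.4 ± 0.945 CPM, and the imprinted RNA KCNQ1OT1 was called higher (140 ± 6.52 CPM in Control, 167 ± 4.38 CPM with DNMT1 knockdown), a value that is uncertain because it lies antisense within KCNQ1. MAGEA3, which shares reads with near-identical family members, was lower by 0.39. Higher and lower members were 8 and 7 of 26 epithelial-mesenchymal genes (adjusted p = 0.592), 12 and 9 of 33 hypoxia and glycolysis genes (0.568) and 7 and 6 of 24 heat shock and immediate early genes (0.964). They were 4 and 1 of 19 enterocyte genes (0.51), 1 and 1 of 12 goblet and enteroendocrine genes (0.827) and 10 and 14 of 81 ribosomal protein genes (0.827), alike when adjusted over the list alone. For small structural RNAs they were 9 and 5 of 49 (7 and 3 adjusted over the list alone; adjusted p = 0.881). Markers of other cell types were higher and lower in 2 and 3 of 7 stromal (2 and 4 adjusted over the list alone), 1 and 0 of 9 leukocyte and 1 and 1 of 7 endothelial genes (adjusted p = 0.881, 0.856 and 0.964). The median, the mean and the test differed in sign for the p53, MHC class I, germline, promoter-methylated, goblet, heat shock, retroviral, small RNA and endothelial lists.

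Of the 6956 changed genes, 3499 were higher and 3457 lower, with a median absolute log2 fold change of 0.24. Of all changed genes, 55.1% differed by less than 1.2-fold. At least 2-fold changes numbered 325, of which 282 were higher. Of those 282, 183 (64.9%) had under 1 CPM in Control, and the 2-fold count was 127 among genes with a mean of at least 2 CPM. With the 6 libraries regrouped, camera at its preset correlation called up to 9 lists while edgeR called 0 genes. Each regrouping holds both groups on each side in unequal number, so part of their difference remains. Those list calls therefore cannot be read as false calls. With DNMT1 knockdown 0 of the 12 lists passed with an estimated correlation, so the list calls are not firm evidence by themselves.

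Against Control, DNMT3B knockdown changed 7949 genes (47.7%), and p53 target genes rose together. PLK2 (chromosome 5, 58453982 to 58460086), a polo-like kinase, rose from 43.6 ± 1.62 to 97.8 ± 1.92 CPM (log2 fold change 1.17 ± 0.041, n = 3 per group, edgeR adjusted p = 6.68e-21). CDKN1A (chromosome 6, 36676463 to 36687332), which encodes the cell cycle inhibitor p21, rose from 146 ± 6.21 to 253 ± 4.4 CPM, and the stress cytokine GDF15 rose to 169 ± 6.57 CPM (log2 fold change 0.74). RUNX2 (chromosome 6, 45328330 to 45551082), a transcription factor of bone development, rose from 2.69 ± 0.583 to 23.6 ± 1.01 CPM (8.85-fold). With DNMT1 knockdown RUNX2 also rose, 6.94-fold to 18.5 ± 1.63 CPM. NRP1 fell 4.58-fold to 28.9 ± 1.91 CPM, and SMAD7 (chromosome 18, 48919853 to 48950965), an inhibitor of TGF-beta signalling, fell from 19.2 ± 0.496 to 6.72 ± 0.403 CPM.

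CLSTN2 (37.5-fold, to 17.7 ± 0.671 CPM), LYPLAL1-AS1 (17-fold), ZC3H11B (10.5-fold) and TGFB2 (10.1-fold, to 17.7 ± 0.353 CPM) were again among the largest rises. B3GALT5, a glycosyltransferase, rose 9.04-fold to 5.98 ± 0.423 CPM, and GRIN2B, an NMDA receptor subunit, rose 8.86-fold to 10.5 ± 0.11 CPM. Both rose with DNMT1 knockdown too, B3GALT5 4.33-fold and GRIN2B 6.98-fold. The remaining large falls were in SAMD11 (3.05-fold lower), CD36 (2.92-fold), ARHGAP24 (2.6-fold), ATOH8 (2.49-fold), FOXP2 (2.47-fold) and STOX1 (2.44-fold). CDKN2A (chromosome 9, 21967752 to 21995324), which encodes p16 and p14ARF and is often methylated in colorectal cancer, fell from 63.5 ± 3.56 to 29.0 ± 0.71 CPM. From the same list of promoter-methylated genes, TMEFF2 rose 3.11-fold and RASSF2 1.64-fold.

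Of 30 p53 target genes, 23 rose and 0 fell with DNMT3B knockdown (24 and 0 adjusted over the list alone), with a median log2 fold change of 0.33 (camera adjusted p = 4.29e-11), and this list passed with an estimated correlation too (adjusted p = 0.00556). MDM2, which encodes a ubiquitin ligase, rose from 333 ± 6.53 to 445 ± 11.8 CPM. G2/M genes rose in 26 of 43 cases and fell in 4 (27 and 5 adjusted over the list alone; adjusted p = 1.34e-05; adjusted p = 0.203 with an estimated correlation). The rises included KIF20A (0.35), CCNB2 (0.34) and ANLN (0.32). S phase and DNA replication genes fell in 37 of 48 cases and rose in 1, also adjusted over the list alone (adjusted p = 9.08e-09; adjusted p = 0.194 with an estimated correlation). RRM2 fell from 345 ± 7.08 to 219 ± 7.09 CPM, RFC5 from 83.3 ± 0.82 to 51.3 ± 1.14 CPM and TYMS from 84.4 ± 4.7 to 57.0 ± 3.14 CPM. Replication-dependent histone genes fell in 24 of 43 cases and rose in 0 (27 and 0 adjusted over the list alone; adjusted p = 6.92e-07; adjusted p = 0.455 with an estimated correlation). H4C1 (-0.81) and H3C13 (-0.65) were among them, with the same uncertainty from near-identical copies.

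Proteasome and lipid synthesis genes fell with DNMT3B knockdown as well. Of the 39 proteasome subunits, 27 fell and 1 rose (28 and 2 adjusted over the list alone; adjusted p = 2.01e-06; adjusted p = 0.455 with an estimated correlation). PSMB5 fell from 117 ± 4.52 to 71.8 ± 7.64 CPM and PSMA2 from 51.3 ± 4.89 to 36.0 ± 2.52 CPM. Cholesterol and fatty acid genes fell in 23 of 33 cases and rose in 2, also adjusted over the list alone (adjusted p = 1.04e-08; adjusted p = 0.194 with an estimated correlation). HMGCS1, an early enzyme of the mevalonate pathway, had a log2 fold change of -0.74, and the desaturase FADS1 fell from 138 ± 5.54 to 93.0 ± 0.974 CPM. SREBF2, the main transcription factor of cholesterol synthesis, fell from 560 ± 9.71 to 424 ± 10.5 CPM. The unfolded protein and integrated stress response list had 19 of 33 genes lower and 6 higher (21 and 6 adjusted over the list alone; adjusted p = 0.0091; adjusted p = 0.405 with an estimated correlation). PSAT1 fell by 0.48, whereas ATF3 rose from 13.1 ± 0.843 to 23.1 ± 2.12 CPM and DDIT4 from 126 ± 4.37 to 175 ± 11.1 CPM.

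Enterocyte, ribosomal protein and immediate early lists rose with DNMT3B knockdown. Enterocyte genes rose in 9 of 19 cases and fell in 1, also adjusted over the list alone (adjusted p = 0.0183; adjusted p = 0.194 with an estimated correlation). The brush border peptidase DPP4 rose from 5.55 ± 0.754 to 9.87 ± 0.296 CPM and CEACAM1 from 0.565 ± 0.0391 to 1.89 ± 0.19 CPM. Ribosomal protein genes rose in 38 of 81 cases and fell in 7 (39 and 7 adjusted over the list alone; adjusted p = 5.77e-05; adjusted p = 0.797 with an estimated correlation). RPL37 was at 0.46, and pseudogene copies leave single values uncertain. Fry did not call the ribosomal protein list (fry adjusted p = 0.151). DNMT3B knockdown replicate 2 was the shallowest library and had the highest ribosomal protein share (3.47% of counts against 2.97 to 3.19% in the others). Without it both lists missed the threshold (adjusted p up to 0.053 for enterocyte genes and 0.0541 for ribosomal protein genes). Heat shock and immediate early genes rose in 12 of 24 cases and fell in 4 (12 and 5 adjusted over the list alone; adjusted p = 0.0424; adjusted p = 0.455 with an estimated correlation), including EGR1 (0.44) and MYC (0.28). This heat shock call was lost without Control replicate 1 or 2, without DNMT3B knockdown replicate 2 and without a low-count filter (adjusted p up to 0.114).

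Other lists did not pass the test with DNMT3B knockdown. Members higher and lower were 10 and 13 of 42 interferon-stimulated genes (adjusted p = 0.773). Within that list ISG15, a ubiquitin-like modifier, fell from 31.9 ± 2.49 to 22.1 ± 2.72 CPM, while TRIM22, an antiviral ubiquitin ligase, rose 5.54-fold to 1.17 ± 0.279 CPM. Higher and lower members were 14 and 9 of 39 promoter-methylated genes (0.687), 7 and 8 of 18 MHC class I genes (0.804), and 5 and 8 of 22 WNT and stem cell genes (0.89). They were 9 and 10 of 26 epithelial-mesenchymal genes (0.837), 6 and 15 of 52 oxidative phosphorylation genes (0.508), 100 and 82 of 392 ZNF genes (0.589) and 1 and 1 of 9 retroviral genes (0.837). Each of these was alike when adjusted over the list alone. They were 9 and 12 of 34 imprinted genes (11 and 13 adjusted over the list alone; 0.804), 2 and 5 of 18 germline genes (2 and 4; 0.73), and 8 and 10 of 26 DNA methylation genes (9 and 10; 0.687). They were 4 and 2 of 12 goblet and enteroendocrine genes (4 and 3; 0.508), 8 and 5 of 23 NF-kB genes (8 and 6; 0.717), 13 and 9 of 33 hypoxia genes (13 and 11; 0.268) and 9 and 5 of 49 small structural RNAs (8 and 5; 0.73). KLF4, a factor of goblet cell differentiation, rose from 24.6 ± 0.857 to 46.9 ± 2.47 CPM, and to 55.2 ± 0.551 CPM with DNMT1 knockdown. The methyl-binding protein gene MBD3 fell from 196 ± 9.44 to 137 ± 2.32 CPM. Stromal, leukocyte and endothelial markers were higher and lower in 4 and 1 of 7, 3 and 0 of 9 (2 and 0 adjusted over the list alone) and 2 and 2 of 7 cases (adjusted p = 0.121, 0.268 and 0.804). COL1A1 rose from 17.6 ± 2.15 to 27.5 ± 0.611 CPM and the lysosomal protein gene CD68 from 17.7 ± 0.54 to 32.9 ± 2.44 CPM. The median, the mean and the test differed in sign for the DNA methylation, interferon, MHC class I, germline and imprinted lists.

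Of the 7949 changed genes, 3850 were higher and 4099 lower, with a median absolute log2 fold change of 0.27, and 48% differed by less than 1.2-fold. At least 2-fold changes numbered 421, of which 362 were higher, and 246 of those 362 (68%) had under 1 CPM in Control. The 2-fold count was 129 among genes with a mean of at least 2 CPM and 670 with no low-count filter. Of the 10 lists called, 1 passed with an estimated correlation. Regroupings of these libraries in which edgeR called 0 genes gave 5 to 12 list calls by camera. Such regroupings keep part of the difference between the groups, so these calls need not be false.

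**Figure D2:**
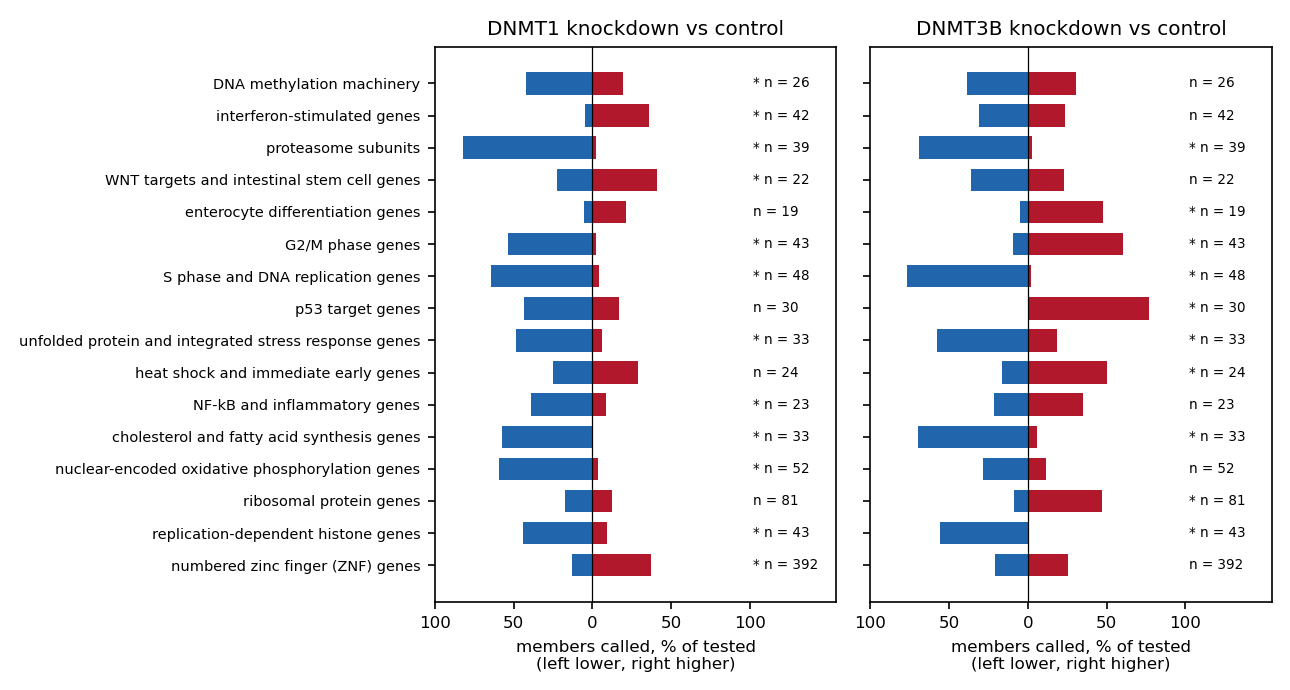
Share of tested members of each list called higher (red, to the right) or lower (blue, to the left) by edgeR, in percent, for DNMT1 knockdown and DNMT3B knockdown against Control, with n the tested members. An asterisk marks lists called by camera at its preset correlation, and the p53 target list stands at 23 of 30 members higher and 0 lower with DNMT3B knockdown.

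Both knockdowns raised CLSTN2, LYPLAL1-AS1, ZC3H11B and TGFB2 and lowered NRP1, CD36, ARHGAP24, NR5A2 and GLIPR1, which are among the genes with the largest changes common to both. NR5A2, a nuclear receptor of gut and liver, fell from 122 ± 1.65 to 69.9 ± 0.663 CPM with DNMT1 knockdown and to 69.7 ± 1.64 CPM with DNMT3B knockdown (n = 3 per group, edgeR adjusted p = 1.96e-18 and 2.87e-18). GLIPR1 fell from 32.8 ± 2.65 to 16.0 ± 0.744 and 19.2 ± 0.465 CPM, and ARHGAP24, a GTPase-activating protein for Rac, from 31.6 ± 1.21 to 12.3 ± 0.222 and 12.1 ± 0.23 CPM. In all, 3482 genes changed in the same direction in both, 1702 higher and 1780 lower, where independent lists would share 809 and 851. Another 796 changed in opposite directions, fewer than independent lists would give. Among genes changed at least 2-fold, 156 were higher in both and 6 lower in both, where independent lists would share 6.13 and 0.152.

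Because both comparisons use the same 3 Control libraries, unchanged groups were simulated against those libraries 20 times. With no gene changed such groups give no shared calls by construction, so they were used for correlation, sign and covariance alone. Across genes the log2 fold changes correlated at 0.599, where the simulations gave 0.425 to 0.460, and their signs matched in 66.1% of genes, where the simulations gave 64.3 to 65.8%. The covariance was 0.0933 against 0.00727 to 0.00816 in the simulations, a difference of 0.0857 from the simulated median. With 3 libraries the controls could not be split, so part of the excess in shared calls may come from the shared controls.

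**Figure D3:**
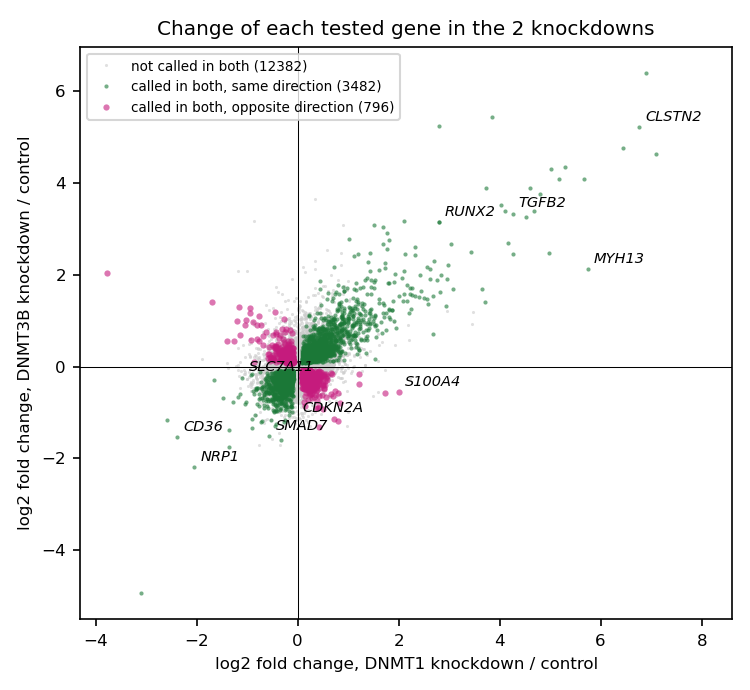
Log2 fold change against Control of each tested gene with DNMT1 knockdown (x axis) and DNMT3B knockdown (y axis), 1 point per gene. Green points are the 3482 genes changed in the same direction in both and magenta points the 796 changed in opposite directions, with CLSTN2 at the upper right and NRP1 at the lower left.

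Compared directly, DNMT1 knockdown and DNMT3B knockdown cells differed in 7534 genes (45.2%), with p53 target and G2/M genes lower in the DNMT1 knockdown. Of 30 p53 target genes, 25 were lower and 2 higher with DNMT1 knockdown, also adjusted over the list alone, by a median log2 of -0.45 (camera adjusted p = 9.59e-15; adjusted p = 0.00264 with an estimated correlation). For G2/M genes, 35 of 43 were lower and 1 higher (37 and 1 adjusted over the list alone), by a median of -0.25 (adjusted p = 9.2e-15; adjusted p = 0.0474 with an estimated correlation). S100A4 (chromosome 1, 153543621 to 153545806), a calcium-binding protein linked to metastasis, was at 17.4 ± 1.09 CPM with DNMT1 knockdown and 3.00 ± 0.694 CPM with DNMT3B knockdown (log2 difference 2.55, n = 3 per group). The water and glycerol channel AQP3 was at 15.6 ± 1.24 and 3.15 ± 0.0814 CPM, and BST2 at 4.03 ± 0.49 and 0.734 ± 0.124 CPM.

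MYH13 (log2 difference 3.61) and ALDH1L1, a folate enzyme (2.53), were the other named genes higher with DNMT1 knockdown. HKDC1, a hexokinase (-2.22), MUC19 (-2.15), DES (-2.10), SUCNR1 (-2.04) and TMEFF2 (-2.03) were higher with DNMT3B knockdown, each at 2.09 to 3.25 CPM there. Among the lists, interferon-stimulated genes were higher with DNMT1 than with DNMT3B knockdown in 20 of 42 cases and lower in 4 (20 and 5 adjusted over the list alone; adjusted p = 0.0339; adjusted p = 0.218 with an estimated correlation). The call was lost without DNMT3B knockdown replicate 2 (adjusted p up to 0.0667). ZNF genes were higher in 138 of 392 cases and lower in 53 (141 and 57 adjusted over the list alone; adjusted p = 0.0315; adjusted p = 0.29 with an estimated correlation). Histone genes were higher in 23 of 43 cases and lower in 1, also adjusted over the list alone (adjusted p = 0.00159; adjusted p = 0.59 with an estimated correlation). Without DNMT3B knockdown replicate 1 the adjusted p was up to 0.0509.

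Ribosomal protein genes were lower with DNMT1 than with DNMT3B knockdown in 44 of 81 cases and higher in 0 (47 and 0 adjusted over the list alone; adjusted p = 7.8e-07; adjusted p = 0.59 with an estimated correlation). Oxidative phosphorylation genes were lower in 23 of 52 cases and higher in 1 (24 and 1 adjusted over the list alone; adjusted p = 0.0022; adjusted p = 0.59 with an estimated correlation). NF-kB genes were lower in 9 of 23 cases and higher in 2, also adjusted over the list alone (adjusted p = 0.0182; adjusted p = 0.339 with an estimated correlation). Heat shock and immediate early genes were lower in 14 of 24 cases and higher in 2 (14 and 3 adjusted over the list alone; adjusted p = 0.0135; adjusted p = 0.339 with an estimated correlation). Unfolded protein and stress response genes were lower in 16 of 33 cases and higher in 9, also adjusted over the list alone (adjusted p = 0.0475; adjusted p = 0.494 with an estimated correlation). That call was lost without Control replicate 3, DNMT1 knockdown replicate 3 or DNMT3B knockdown replicate 2 and under other low-count filters (adjusted p up to 0.0746). Proteasome subunits, which fell in both knockdowns, were higher in 5 and lower in 7 of 39 cases (5 and 6 adjusted over the list alone; adjusted p = 0.985). S phase genes were higher in 14 and lower in 6 of 48 (13 and 5 adjusted over the list alone; adjusted p = 0.121).

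Of the 7534 genes, 4047 were higher and 3487 lower with DNMT1 knockdown, and at least 2-fold differences numbered 307, 133 higher and 174 lower. The 2-fold count was 79 among genes with a mean of at least 2 CPM, 184 among genes with at least 1 CPM in 3 libraries and 469 with no low-count filter. Against the 10 lists called here, regroupings of these libraries in which edgeR called 0 genes gave 3 to 13 list calls by camera. They too keep part of the difference, so they do not show how many list calls would be false. Fry did not call the ribosomal protein and oxidative phosphorylation lists here (fry adjusted p = 0.14 and 0.137).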

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

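In this part the comparison of the covariance with simulated unchanged groups, the neighbours of all shared genes and the shares above and below 1 CPM were tests chosen only after the result was seen, and thinning of the libraries was added after the data had been seen.

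The 2 knockdowns moved 796 genes in opposite directions, each called against Control in both comparisons. All were also called in the direct comparison by edgeR, which follows from opposite calls against the same Control and adds no support. Independent lists would share 1660 genes in the same direction. Rises and falls were near equal in number, so about as many would be opposite, and 796 is a deficit rather than an excess. Of these, 21 changed at least 1.5-fold in both. Genes chosen from them after their values were seen were SMAD6, an inhibitor of BMP signalling, at 12.4 ± 0.591 CPM in Control, 22.0 ± 0.802 with DNMT1 knockdown and 7.21 ± 0.274 with DNMT3B knockdown, the carbonic anhydrase gene CA9 at 3.00 ± 0.26, 4.88 ± 0.148 and 1.91 ± 0.17 CPM, and SUN3 at 7.57 ± 0.419, 4.599 ± 0.395 and 14.2 ± 1.55 CPM (n = 3 per group). Of the p53 target genes named by rule, PLK2 (0.39 and 1.17) and EDA2R (0.0654 ± 0.0298 CPM in Control, 1.26 ± 0.13 and 0.432 ± 0.271 CPM) rose with both knockdowns, EDA2R more with DNMT1 knockdown (adjusted p = 0.000118 in the direct comparison), while CDKN1A, GDF15 and MDM2 fell with DNMT1 knockdown (log2 fold change -0.16, -0.11 and -0.43) and rose with DNMT3B knockdown (0.79, 0.74 and 0.42).

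The p53 target list (median log2 difference -0.449) and the G2/M list (median -0.254) differed between the knockdowns by the test of the difference itself. The tables argue against 2 technical explanations, GC content or transcript length and a divergent library. After removal of a smooth trend on GC content and transcript length the medians were -0.415 and -0.229, and without DNMT3B knockdown replicate 2 the lists kept 96.7% and 94% of their size. With every library thinned to the smallest total the lists kept at least 99%. Thinning leaves each gene's expected share of its library unchanged, so this last value could not weigh depth. That lower DNMT3B acts on p53 target and G2/M genes in a way lower DNMT1 does not remains a hypothesis. It was found and tested on the same libraries. DNMT3A mRNA also fell with DNMT3B knockdown, to 68.9% of Control, and the design does not separate that fall from the fall of DNMT3B. An effect of the particular knockdown sequences or of the cell populations that grew out under selection could give the same pattern and was not tested.

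In both knockdowns, changes of at least 2-fold were mostly rises, 282 of 325 with DNMT1 knockdown and 362 of 421 with DNMT3B knockdown. Among genes with at least 1 CPM in both groups compared, a limit that treats rises and falls alike, the share that was higher was 87.6% and 84.1%, which argues against low counts as the cause there. After thinning to the smallest total the lower of the shares was 85.9%, so rises still prevailed among calls made at equal totals. Thinning leaves each gene's expected share of its library unchanged, so it could not weigh an effect of depth on the fold changes themselves. The median log2 fold change of tested neighbours within 1 Mb was 0.0361 and 0.0288, which argues against a different copy number in the Control cells. Under 1 CPM in the lower group, where 183 of 212 and 246 of 283 changes were rises (86.3% and 86.9%), counts near the floor leave low counts open as an explanation. Release of genes from methylation may account for rises but was not tested, since methylation was not measured in these libraries.

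Beside the 3482 genes changed alike in both knockdowns, the covariance of log2 fold changes over all tested genes was 0.09331. The highest simulated for shared controls was 0.00816. Genes with large changes weigh most in a covariance, so it says little about the many small shared changes. Signs matched in 66.1% of all tested genes, only slightly above the 64.3 to 65.8% of the simulations. Shared genes kept 99.9% of their median change after thinning. Since thinning leaves each gene's expected share of its library unchanged, that value could not weigh depth. At equal totals 3039 genes were still called alike in both. Against copy number in the Control cells, the neighbours within 1 Mb changed by a median of 3.33% of the gene's own change over the shared genes (quartiles -8.9 to 18.2%), and by 0.0441 around those changed at least 2-fold in both (quartiles -0.00909 to 0.118). Of 100 splits of the 9 libraries into 3 groups, 2 gave as many shared genes. They were the real one and 1 that kept the groups intact with another group as control (4279). The highest with libraries mixed was 1044. Mixing puts differences between the groups into the spread within them, which lowers the calls, so the mixed splits cannot weigh chance. Genes that answer to a lower level of either enzyme could give this pattern. So could genes that answer to a handling of the knockdown cells that the Control cells did not share. The design does not separate them.

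The 10 splits of 6 libraries are too few for a share under 0.05. All but the real one also mix the groups unevenly. Part of the difference stays between the sides and the rest adds to the spread within them, so their counts are not those of unchanged groups. For DNMT1 knockdown against Control 1 of the 10 splits, the real one, gave as many as 6956 genes, 325 genes changed at least 2-fold and 12 lists, with 0, 0 and 9 the highest of the others. For DNMT3B knockdown the real counts were 7949 genes, 421 genes and 10 lists, with 0, 0 and 12 the highest of the others, so that 2 of the 10 splits gave as many lists. For the direct comparison they were 7534 genes, 307 genes and 10 lists, with 0, 0 and 13 the highest of the others.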

How the results depend on the processing

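Thinning all libraries to the smallest total was chosen only after the data had been seen. Every setting kept the direction of DNMT1 in its knockdown and of DNMT3B in its own, and left the counts of changed genes and of genes changed alike in both knockdowns within 1.5 times the reported ones. DESeq2 called 5718, 6706 and 6323 genes for DNMT1 knockdown, DNMT3B knockdown and the direct comparison, and the thinned libraries gave 6203, 7246 and 7101. Leaving out each library in turn gave 5737 to 7111, 7032 to 8079 and 6658 to 7602 genes. The counts of genes changed at least 2-fold depended on the low-count filter by construction, since it sets which weakly expressed genes are tested. With no filter they were 670 for DNMT3B knockdown and 469 for the direct comparison, with at least 1 CPM in 3 libraries 267 and 184, and with a mean of at least 2 CPM 127 for DNMT1 knockdown, 129 for DNMT3B knockdown and 79 for the direct comparison. Gene lists called fell from 12 to 0 (DNMT1 knockdown) and from 10 to 1 (DNMT3B knockdown) with an estimated inter-gene correlation, which replaces the preset value of 0.01, and fry, which asks a different question, called 17 for DNMT3B knockdown.

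The replicate numbers did not pair the libraries. Deviations from the group means correlated at -0.0615 to 0.0425 between libraries with the same number (9 pairs) and at -0.0393 to 0.0598 between others. With the replicate number as a block (replicate block), 6796, 7789 and 7379 genes were called and the same number of lists, 12 and 10.

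Of 5293 values for 269 results on single genes over 20 settings, 5266 kept their direction and side of the threshold, 26 lost the call, 1 gained it and 0 reversed. Losses among genes named here were DNMT1 in the DNMT3B knockdown (above), ANLN with DNMT1 knockdown, KRT38 and MYH4 with DNMT3B knockdown, and KRT32 in the direct comparison when thinned (adjusted p = 0.0619). Depth limits genes near the floor of 0.0891 to 0.16 CPM, and most 2-fold rises start from under 1 CPM.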

Other observations

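The tests of neighbouring genes were chosen only after the result was seen, and the genes named in the first paragraph and the last were chosen after their values were seen.

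Hair keratin genes that lie side by side on chromosome 17 (41420547 to 41489910, GRCh38) were higher together in both knockdowns. KRT37 went from 0.773 ± 0.127 CPM in Control to 2.86 ± 0.293 with DNMT1 knockdown and 1.80 ± 0.291 with DNMT3B knockdown, KRT32 from 2.63 ± 0.681 to 6.97 ± 0.511 and 5.40 ± 0.174, KRT35 from 1.53 ± 0.17 to 4.05 ± 0.268 and 3.39 ± 0.677, and KRT36 from 0.908 ± 0.092 to 2.45 ± 0.468 and 2.16 ± 0.351 (n = 3 per group, edgeR adjusted p of 1.01e-05 or smaller for each). KRT38 rose to 1.87 ± 0.152 with DNMT1 knockdown, and its rise to 1.15 ± 0.0706 with DNMT3B knockdown (adjusted p = 0.0154) was lost with DESeq2 (0.0621), without Control replicate 2 (0.0591) and without DNMT3B knockdown replicate 3 (0.0545). The keratins are similar in sequence, so single values are uncertain. On chromosome 19 the neighbours ZNF134 and ZNF211 rose with both knockdowns, ZNF211 from 0.763 ± 0.179 to 4.26 ± 0.184 and 2.46 ± 0.121 CPM. On chromosome 17 (10300865 to 10549658), the adjacent myosin genes MYH13, MYH8, MYH4 and MYH2 rose with DNMT1 knockdown, MYH8 from 0.0579 ± 0.0466 to 0.655 ± 0.0816 CPM and MYH2 from 0 counts in Control to 0.654 ± 0.125 CPM. With DNMT3B knockdown MYH13 rose to 0.298 ± 0.1 CPM (adjusted p = 0.00296) and MYH2 was at 0.125 ± 0.0787 CPM (adjusted p = 0.00257). MYH8 was at 0.134 ± 0.0497 CPM (adjusted p = 0.179) and MYH4 at 0.141 ± 0.0447 CPM (adjusted p = 0.0129), a call lost with DESeq2 (0.0512), without Control replicate 3 (0.0635), without DNMT3B knockdown replicate 3 (0.0765) and when thinned (0.062). These myosin genes are similar in sequence, and apart from MYH13 their levels with DNMT3B knockdown lay within the range of the 3-count floor, so their values are uncertain.

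Genes at least 2-fold higher lay next to each other more often than chance placement gave. Of 13628 adjacent, non-overlapping pairs of tested genes, 29 were both at least 2-fold higher with DNMT1 knockdown, where 10000 permutations within 10 classes of mean CPM gave a mean of 3.93 and at most 13 (one-sided permutation p = 1e-04, the smallest they can give). With DNMT3B knockdown the numbers were 31 pairs against a mean of 6.56 and at most 17 (one-sided permutation p = 1e-04). Adjacency carried no limit on distance, and a pair counted with DNMT1 knockdown lay 3688776 bases apart. Around genes at least 2-fold higher, tested neighbours within 1 Mb had a median log2 fold change of only 0.0361 and 0.0288. For some pairs rises may spread over short stretches of chromosome, as a hypothesis, although similar gene copies that share reads also lie side by side.

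ZNF genes on chromosome 19, where clusters of them lie, were tested against those elsewhere. With DNMT1 knockdown 72 of 162 (44.4%) rose on chromosome 19 and 73 of 230 (31.7%) elsewhere (two-sided Fisher's exact p = 0.011). Genes of other kinds on chromosome 19 were also higher more often, 264 of 942 (28%) against 3069 of 15176 (20.2%) elsewhere, so the difference may belong to the chromosome rather than to the ZNF genes.

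Several genes typical of colon epithelium had low or no counts in all 9 libraries, here in CPM of the unscaled library total. CEACAM5, which encodes the carcinoembryonic antigen that HT29 is known to produce, ranged from 0 to 0.0533 CPM with 2 counts in all, CEACAM6 from 0 to 0.0412, LGALS4 from 0.0427 to 0.497, CDH17 from 0.256 to 0.783, VIL1 from 0.616 to 1.44 and KRT20 from 0.926 to 2.27 CPM, and TFF3 and FABP1 had 0 counts. In the same libraries CDX2 ranged from 37.2 to 42.6, EPCAM from 222 to 285 and KRT8 from 976 to 1240 CPM. The identity of the line was not tested, since the counts hold no genotype, so the name HT29 rests on the labels and is in doubt from these levels.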
